A study of Arabidopsis thaliana with 16 samples.

How the data were processed

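The series measured mRNA in young Arabidopsis thaliana Columbia-0 seedlings that were moved in the morning to liquid medium with 0 or 100 µM glutathione (GSH, the cell's main soluble thiol) and harvested after 8 or 24 h. Roots and shoots were kept apart, and each was assayed both as total RNA and as polysomal RNA, the RNA recovered from ribosome-loaded fractions of a sucrose gradient per the labels' protocols. The labels give 1 one-colour Agilent array for each of the 16 combinations of fraction, organ, time and treatment, on 4 slides of 4 arrays. Each slide holds both organs and both treatments of 1 fraction at 1 time. The series' design text speaks of independent experiments at each time, and whether their RNA was pooled is not given in the sources used here, so each condition counts as 1 sample.

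Per the file headers, spot intensity was extracted with Agilent Feature Extraction 10.7.1.1, while the submitters' processing notes name version 9.1. The deposited intensity used here, the processed signal, is background-subtracted and detrended within an array per the file headers, and is not scaled between arrays. Other deposited columns hold flags for spots well above background, saturated spots and outliers. The authors' deposited tables list probes with a signed fold change of at least 2 and a p-value per the file headers, together with spot intensity per array; which test gave that p-value is not given in the sources used here. Per the labels' protocols, polysomal arrays were calibrated by the share of RNA in polysomes; the values of that share were not used here. The fold column was read only to check its lists against the scanner values, and the p-value column was not used further. In those tables, the columns of every total RNA array hold the values of the partner array, GSH for control and the reverse, in each of the 14 lists of other comparisons, within a tolerance of 0.1%. Those of the polysomal 24 h root arrays do so in 13 of 14, and hold their own values in the list of genes higher in total RNA of roots at 24 h. All measurements therefore come from the scanner files.

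Control spots were left out, and 59 of 43603 probes marked as outliers on any array were left out. The processed signal was averaged over the spots of a probe, then log2-transformed, and the array's 75th percentile over probes was subtracted. Probe loci were named through a RefSeq table of gene names for assembly TAIR10.1, without its coordinates; 34307 probes had 1 locus and 9237 had none and entered no gene test. A gene was represented by its brightest probe over the 16 arrays, giving 25414 genes, of which 6916 had several probes. Between 69.4% and 80.4% of the spots of an array were well above background and none was saturated. The small number of arrays limits the precision.

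With 1 array per condition, GSH and control within an organ and time were not tested. Genes at least 2-fold apart in the same direction in both fractions were counted among those well above background on at least 1 array of each fraction, beside the overlap of independent lists (product of list lengths over genes). Gene lists were placed by the percentile of their median among 10000 random lists of the same size matched on mean expression in 20 bins. Effects over several conditions were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjustment at 0.05). Organ-by-time pairs were the block for GSH, time-by-treatment pairs for organ, organ-by-treatment pairs for time, and all 8 conditions for fraction. A gene entered a test if its probe was well above background on at least as many of the comparison's arrays as not. For GSH within an organ, total and polysomal values of a condition were averaged first, since they may share a harvest. These p-values measure the spread between pairs of single arrays, not between replicate plants. The 24 gene lists, which include organ markers, were fixed before the data were examined and tested with camera at a preset correlation of 0.01 and again with an estimated one. With the estimated correlation no list passed, not even the organ markers between roots and shoots, so that setting does not decide for or against a list. Plastid- and mitochondrion-encoded genes were not analysed here.

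Where a probe was not well above background on any array of an arm, the fold is given as "at least": the bright arm's mean against the higher of the dim probe's own signal and the array's lowest signal well above background. Named genes were chosen by a rule fixed before the data were examined. For a test, these are up to 10 genes per direction with the largest change among those past the threshold, in the same direction in every pair, and well above background on every array of the higher arm. For a single comparison, these are up to 8 per direction ranked by the smaller of the changes in the 2 fractions, with both arrays of the higher arm well above background. Up to 4 members of a described list may be named, and glutathione, sulfate and sulfur starvation genes always.

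The fits were tested on simulated arrays with each gene's mean and its moderated spread from the fit, and 200 changed genes per comparison. A changed gene had the same change in all pairs it was set in, so recovery of changes that differ between pairs was not tested. For GSH in total RNA, over 21229 genes, 93 of 100 genes changed 2-fold and 99 of 100 changed 4-fold were recovered; for polysomal RNA, over 21094 genes, 88 and 99. For roots minus shoots, over 21060 genes, 51 and 99 were recovered. Unchanged genes called were 10 for total RNA, 16 for polysomal RNA and 14 for roots minus shoots. In a test of the list percentiles, 4% of 200 unchanged lists of 20 genes fell outside the central 95% and 95.5% of lists shifted by 0.5 lay above the 97.5th percentile. There the genes varied independently, whereas members of a real list may change together. Percentiles of real lists can therefore be extreme more often than this, also without a GSH effect. Alternatives were normexp with an offset of 50, quantile normalization, the mean of all probes of a gene, other filters and fold minimums, limma's intensity trend, the slide as a block, each pair left out, for gene lists too, and either fraction or time alone. Normexp used the median signal of a spot in place of its mean. It moved the median of all genes on the polysomal control arrays of roots at 8 h to -0.85 and of shoots at 24 h to -0.11, against -1.21 to -1.52 on the others. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 was used for the rest.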

Results

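The question was which transcripts respond to added GSH in roots and shoots, and whether their loading onto polysomes responds too. There were 16 arrays, 1 for each combination of total or polysomal RNA, root or shoot, 8 or 24 h, and 0 or 100 µM GSH. Log2 changes below are GSH minus control on arrays scaled to their 75th percentile, and a single change has no replicate check. Both fractions of a condition may share a harvest, so a difference between the single control and GSH samples can appear in both. More shared genes than independent lists would give therefore need not reflect GSH. The pair labelled total RNA of roots at 8 h ran against the other 3 root pairs, and the differences between the arrays labelled polysomal and total had opposite signs at 8 and 24 h; directions drawn from these labels are stated as labelled.

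In roots at 24 h, heat shock genes and the sulfur starvation marker LSU1 were higher with GSH, and jasmonate and iron deficiency genes were lower, in both fractions. ChlAKR (AT2G37770), a chloroplast aldo-keto reductase that removes reactive carbonyls, was 3.69 higher in total RNA and 9.18-fold higher in polysomal RNA. DIN2 (AT3G60140), a dark-inducible beta-glucosidase, was higher by 2.78 and 3.04, and the nitrilase gene NIT4 (AT5G22300) by 2.41 and 2.20. AT1G29100 was 2.27 higher in total RNA and at least 2.82-fold higher in polysomal RNA, AT5G38910 was 1.58 and 2.72 higher, AT2G38823 1.66 and 1.70, and AT3G54530 1.80 and 1.54. AT4G11393 was at least 3.47-fold higher in total RNA and at least 1.4-fold higher in polysomal RNA. Among the lower genes, TAT3 (AT2G24850), a tyrosine aminotransferase gene induced by jasmonate, stood at -1.72 and -1.71, AT3G44870 at -2.09 and -2.41, and AT3G22275 at -1.79 and -2.35. LCR85 (AT4G22210), which encodes a small cysteine-rich protein, was at least 8.00-fold lower in total and at least 6.79-fold lower in polysomal RNA, CYP76C4 (AT2G45550) at least 1.59-fold and 1.68-fold, AT3G50160 at least 1.34-fold and 1.93-fold, and AT3G06880 at least 1.28-fold and 2.52-fold. AT4G37710 was at least 3.90-fold lower in total RNA and stood at -2.52 in polysomal RNA.

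The 22 jasmonate genes had medians of -0.75 in total and -0.54 in polysomal RNA at 24 h in roots, both at percentile 0 of random lists. The repressor gene JAZ10 stood at -1.64 and -1.65, JAZ8 at -0.84 and -1.35, JAZ7 at -0.89 and -0.96, and AOC1, of jasmonate synthesis, at -0.90 and -0.82. All 10 iron deficiency genes were lower in both fractions, with medians of -0.74 and -0.39 at percentile 0. They include the transcription factor gene MYB72 (-1.06 and -0.88), the ferric reductase gene FRO2 (-1.42 and -0.51), BHLH100 (-0.88 and -0.92) and the iron transporter gene IRT1 (-1.27 and -0.08). The 10 heat shock genes lay at percentile 100 with medians of 0.58 and 0.52; HSFA2, a heat shock factor gene, was 1.29 and 1.13 higher and the chaperone gene HSP90.1 0.96 and 0.84. Of the 12 sulfur starvation markers 7 were higher in total and 8 in polysomal RNA (medians 0.11 and 0.09), with LSU1 higher by 1.29 and 1.07 and ATSDI1 by 0.46 and 0.28. Of 38 glutathione S-transferase genes 29 and 20 were higher (medians 0.24 and 0.04), among them GSTU25 (1.63 and 1.25), GSTU11 (0.99 and 0.93) and GSTU22 (0.82 and 0.65). The sulfate assimilation list had medians of -0.12 and -0.03, and the glutathione metabolism list -0.08 and -0.10, with GGT1, a gamma-glutamyl transferase gene, at -0.34 and -0.30. Root markers were lower too, 11 of 17 in total and 13 in polysomal RNA, with medians of -0.27 and -0.10 at percentiles 0.06 and 0.21. In all, 24 genes were at least 2-fold higher and 40 at least 2-fold lower in both fractions, against 0.25 and 0.68 for independent lists, and the changes correlated at r = 0.40 across 21105 genes, which are not independent replicates. The total was 24 with normexp in place of 64.

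In shoots at 8 h, salicylate defence genes and early stress transcription factor genes were lower with GSH, and aliphatic glucosinolate genes were higher. PR1 (AT2G14610), a marker of salicylate signalling, stood at -1.52 in total and -1.29 in polysomal RNA, and the transporter gene ABCG40 (AT1G15520) at -1.53 and -1.45. AT5G41740 stood at -1.23 and -1.35 and the receptor-like protein gene RLP40 (AT3G24982) at -1.10 and -1.21. HAK5 (AT4G13420), a high-affinity potassium transporter gene, was at least 2.14-fold lower in total and at least 1.81-fold lower in polysomal RNA, and GLIP1 (AT5G40990) at least 1.61-fold and 3.97-fold. AGP30 (AT2G33790) was at least 1.26-fold lower in total RNA and stood at -1.07 in polysomal RNA, and AT3G24240 was at least 1.04-fold lower and stood at -1.74. NCED2 (AT4G18350), of abscisic acid synthesis, was at least 1.19-fold and 3.49-fold higher, AT3G51540 at least 1.23-fold and 5.77-fold, AT5G65550 at least 1.48-fold and 4.67-fold, AT4G25580 at least 1.33-fold and 1.72-fold, and AT4G21020 at least 2.20-fold and 1.93-fold. AT3G24420 was 1.09 and 1.15 higher, AT1G11925 1.31 higher and at least 5.26-fold higher, and AT1G52618 at least 2.20-fold higher and 1.64 higher.

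All 14 aliphatic glucosinolate genes were higher in both fractions of shoots at 8 h, with medians of 0.38 and 0.23 at percentiles 100 and 99.99; CYP79F2, which starts core glucosinolate synthesis, was 0.57 and 0.36 higher. The 15 salicylate and pathogen defence genes had medians of -0.28 and -0.37 at percentile 0, with BGL2 at -0.81 and -1.06, WRKY38 at -0.85 and -0.99 and the camalexin gene PAD3 at -0.61 and -0.78. Early stress transcription factor genes had medians of -0.44 and -0.20, including WRKY33 at -0.65 and -0.91 and WRKY40 at -0.70 and -0.56. Of the clock genes, those peaking around dusk had medians of 0.29 and 0.31 and those peaking around dawn -0.28 and -0.36. The dark and sugar starvation list had medians of 0.64 and 0.47, both at percentile 100. The sulfur starvation marker ATSDI1 stood at -0.65 and -0.35 and LSU3 at -0.35 and -0.33. All 12 glutathione metabolism genes were higher in total RNA and 5 in polysomal RNA, with medians of 0.12 and -0.01. Both fractions shared 9 higher and 16 lower genes at 2-fold, against 0.13 and 0.16 for independent lists, with r = 0.31 across 19525 genes. With normexp no gene was shared, and with all 4 arrays well above background 10 were.

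In shoots at 24 h, genes of sugar starvation were higher and dawn clock and stress transcription factor genes lower with GSH. AT1G50040 was higher by 2.85 and 2.35, PHI-1 (AT1G35140), a phosphate-induced gene, by 2.03 and 2.06, and XTH25 (AT5G57550), a xyloglucan-modifying enzyme gene, by 2.04 and 1.87. AT5G25240 was higher by 1.98 and 1.57, COR27 (AT5G42900), a cold-regulated gene, by 1.76 and 1.69, AT3G19680 by 1.83 and 1.42 and EXLA1 (AT3G45970), an expansin-like gene, by 1.37 and 1.53. AT1G66860 was 1.52 higher in total RNA and at least 4.1-fold higher in polysomal RNA, but -0.85 on average under normexp. The B-box gene BBX30 (AT4G15248) stood at -2.08 and -2.22, AT2G15020 at -1.97 and -2.69, and AT3G09450 at -1.89 and -1.77. AT2G27270 stood at -2.03 and was at least 4.15-fold lower, PMT1 (AT2G16120) was at least 2.17-fold lower and stood at -1.88, AT2G26450 was at least 1.1-fold and 2.97-fold lower, and AT5G37473 at least 1.26-fold and 2.91-fold. AT3G26880 was at least 2.39-fold lower in polysomal RNA.

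All 3 measured genes of dark and sugar starvation were higher in shoots at 24 h, with medians of 1.17 and 1.02 (1.02 and 0.87 after quantile normalization): ASN1, an asparagine synthetase gene, by 1.17 and 1.53, DIN10 by 1.19 and 1.03 and SEN1 (AT4G35770) by 0.74 and 0.91. The 5 dawn clock genes had medians of -0.67 and -0.86, with PRR9 at -1.23 and -2.24 and LHY at -0.59 and -1.11. The 9 early stress transcription factor genes had medians of -0.51 and -0.34, with RRTF1 at -1.18 and -1.10. All 10 endoplasmic reticulum chaperone genes were lower in both fractions, with medians of -0.26 and -0.27. The aliphatic glucosinolate genes, higher at 8 h, were lower at 24 h, all 14 in total RNA (median -0.40) and 11 in polysomal RNA (median -0.17); the difference between times was not tested. Photosynthesis genes had a polysomal median of -0.64 that became 0.02 after quantile normalization. In total RNA 21 of 24 were lower, with a median of -0.13 that became -0.04 after quantile normalization. In both fractions 50 genes were higher and 36 lower, against 1.63 and 2.51 for independent lists, with r = 0.35 across 19679 genes. The normexp counts were 23 and 15, in all 38 against 18.1 for independent lists, where the 86 genes stand against 4.15. The polysomal pair had the widest spread between probes of one gene, an SD of 0.64 against 0.16 in total RNA of roots at 24 h, and in it RLP23 and AT5G23110 stood at -13.77 and -8.26 and AT3G04320 was at least 33736-fold lower. These 3 genes, named after their values were seen, stood at 8.11, 9.28 and 8.08 on its control array and at most at -5.47, 1.06 and 2.39 on any other array.

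In roots at 8 h, sulfur starvation, glutathione S-transferase and iron deficiency genes were higher with GSH in polysomal RNA and lower on the arrays labelled total RNA. Of 20700 genes, 43.8% had the same sign in both fractions, with a rank correlation of -0.19 across genes. Sulfur starvation markers had a median of 0.48 in polysomal RNA and -0.30 on the arrays labelled total RNA, percentiles 100 and 0. LSU1 stood at 1.44 and -1.32, ATSDI1 at 1.06 and -0.61, and LSU3 at 1.05 and -0.65. Glutathione S-transferase genes had medians of 0.44 and -0.27, with GSTF7 at 2.32 and -1.81, GSTF6 at 2.08 and -1.67 and GSTU22 at 1.26 and -1.24. Iron deficiency genes had medians of 0.60 and -0.26, with IRT1 at 1.14 and -0.45. Only 2 genes were higher and 19 lower in both fractions at 2-fold, while 135 were 2-fold apart in opposite directions, against 3.05 for independent lists; r was -0.36 across 20700 genes. PAP6 (AT1G56360), a purple acid phosphatase gene, was at least 1.35-fold higher in total and 1.06-fold higher in polysomal RNA, and AT2G43440 at least 1.40-fold and 1.51-fold; both were lower under normexp, at -1.52 and -1.54 on average. AT3G21940 was at least 2.43-fold and 2.53-fold lower, AT2G22160 at least 2.22-fold and 2.64-fold, AT1G58525 at least 2.38-fold and 1.64-fold, and AT4G26460 at least 1.16-fold and 2.5-fold. AT2G20921 was at least 3.57-fold lower and stood at -1.56, RALFL5 (AT1G35467), which encodes a signalling peptide, was at least 1.86-fold lower and stood at -1.89, AT4G20470 was at least 1.63-fold lower and stood at -1.47, and AT4G15953 stood at -1.33 and -1.26. The count shared by both fractions was 21 against 2.45 for independent lists, 9 against 2.39 after quantile normalization, and 23, all lower, against 16.9 with normexp.

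**Figure D1:**
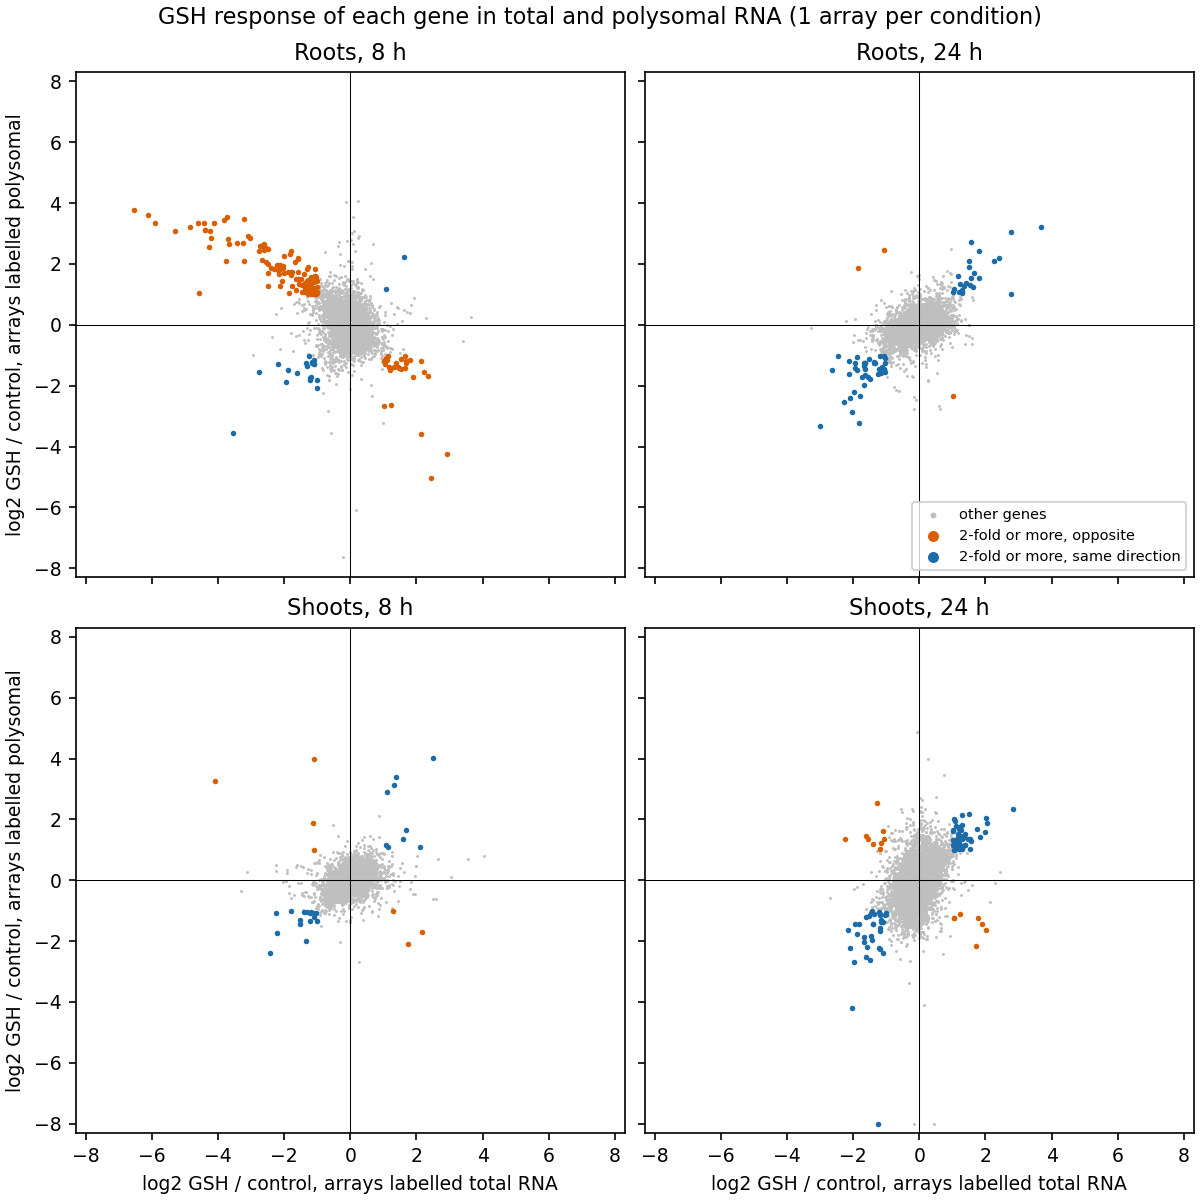
Log2 GSH over control of each gene on the arrays labelled total RNA (x axis) and polysomal RNA (y axis), with genes at least 2-fold apart in both fractions coloured by whether their directions match; 3 genes of polysomal RNA in shoots at 24 h lie beyond -8 or 8 and are drawn at the border. In roots at 8 h, 135 genes had opposite directions and 21 the same, whereas 64, 25 and 86 had the same direction in roots at 24 h, shoots at 8 h and shoots at 24 h.

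**Figure D2:**
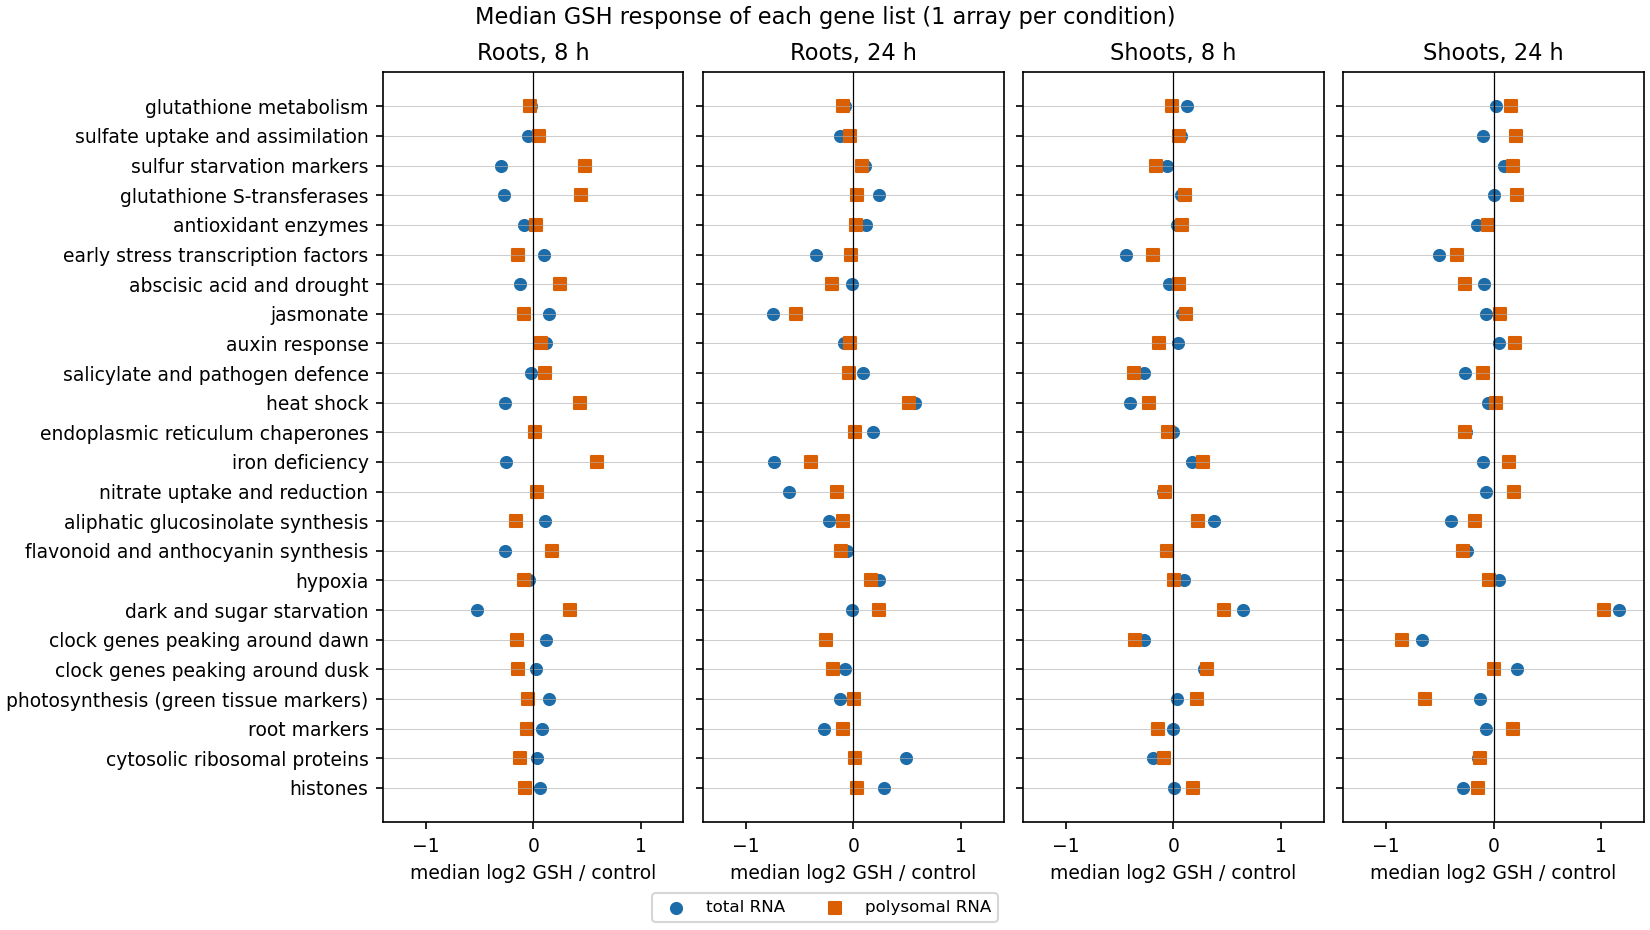
Median log2 GSH over control of the 24 gene lists (vertical axis) in total RNA (circles) and polysomal RNA (squares), 1 panel per organ and time. The dark and sugar starvation list was highest in shoots at 24 h, at 1.17 and 1.02. The lowest median in total RNA was that of the jasmonate list in roots at 24 h, at -0.75. In polysomal RNA it was that of clock genes peaking around dawn in shoots at 24 h, at -0.86.

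Averaged over organs and times, no gene passed the test for GSH. Limma called 0 of 21229 genes in total RNA, where 802 had an unadjusted p under 0.05 against 1061 expected with no change. In polysomal RNA it called 0 of 21094, where 1181 had such a p against 1055 expected. Within the slides of 8 and 24 h it also called 0, with 1134 and 1231 genes at an unadjusted p under 0.05 in total and 747 and 706 in polysomal RNA. In total RNA all 9 early stress transcription factor genes were lower (median -0.28, camera adjusted p = 0.00012, adjusted p = 0.89 with an estimated correlation), as were all 5 dawn clock genes (median -0.35, adjusted p = 0.00026, and 0.89 with an estimated correlation). Adjusted over the list alone, 1 dawn clock gene and 0 stress factor genes passed. Flavonoid (12 of 12 lower, median -0.14, adjusted p = 0.0065), jasmonate (18 of 22 lower, median -0.13, adjusted p = 0.012) and iron deficiency genes (10 of 10 lower, median -0.20, adjusted p = 0.023) passed too. Each was at adjusted p = 0.89 with an estimated correlation, and none of their genes passed when adjusted over the list alone. Without the root 24 h pair jasmonate stood at 0.055 (adjusted p = 0.38) and iron deficiency at 0.023 (adjusted p = 0.91, the test's direction staying lower). Without the root 8 h pair iron deficiency stood at -0.18 (adjusted p = 0.058) and flavonoid genes at -0.07 (adjusted p = 0.23). In polysomal RNA, 32 of 38 glutathione S-transferase genes were higher (median 0.16, adjusted p = 4.0e-07, adjusted p = 0.78 with an estimated correlation), and 10 of 12 sulfur starvation markers (median 0.19, adjusted p = 0.011, adjusted p = 0.78 with an estimated correlation). Without the root 8 h pair, 8 of the 12 sulfur starvation markers were higher (median 0.15) and the list no longer passed, at adjusted p = 0.46. No glutathione S-transferase gene and no sulfur starvation marker passed when adjusted over the list alone. Also in polysomal RNA, all 5 dawn clock genes (median -0.45, adjusted p = 0.0023), 36 of 46 ribosomal protein genes (median -0.09, adjusted p = 0.0050) and 8 of 9 early stress factor genes (median -0.25, adjusted p = 0.0065) were lower. All 4 sugar starvation genes (median 0.57, adjusted p = 0.0050) and 14 of 21 sulfate genes (median 0.11, adjusted p = 0.048, but adjusted p = 0.10 after quantile normalization) were higher. All 5 lists were at adjusted p = 0.78 with an estimated correlation, and 2, 0, 1, 1 and 0 genes passed when adjusted over the list alone. The stress factor list did not pass without the shoot 8 h or shoot 24 h pair (adjusted p = 0.059 and 0.092). The sulfate list did not pass without these pairs or the root 8 h pair either (adjusted p = 0.11, 0.22 and 0.068). The glutathione metabolism list did not pass in either fraction, with medians of -0.01 and 0.06.

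With total and polysomal values averaged, limma called 0 of 21001 genes for GSH in roots and 0 of 20029 in shoots. An unadjusted p under 0.05 was found for 496 and 1006, against 1050 and 1001 expected with no change. In roots 21 of 22 jasmonate genes were lower (median -0.25, camera adjusted p = 1.2e-06, adjusted p = 0.78 with an estimated correlation), and 0 passed when adjusted over the list alone. This rests on 24 h: without that pair 13 of 22 were higher (median 0.018, adjusted p = 0.91), and at 8 h the medians were 0.15 in total RNA, with 17 higher (percentile 99.87), and -0.09 in polysomal RNA, with 11 higher and 11 lower. The root values include the doubted total RNA pair at 8 h. Glutathione S-transferase (30 of 38 higher, median 0.13, adjusted p = 2.2e-05) and heat shock genes (9 of 10 higher, median 0.34, adjusted p = 2.2e-05) passed in roots. So did ribosomal protein (41 of 46 higher, median 0.09, adjusted p = 0.0013) and histone genes (23 of 25 higher, median 0.08, adjusted p = 0.023, but adjusted p = 0.092 after quantile normalization). Iron deficiency (9 of 10 lower, median -0.20, adjusted p = 0.041, but adjusted p = 0.059 after quantile normalization) and nitrate genes (5 of 5 lower, median -0.19, adjusted p = 0.041) passed too. With an estimated correlation these 6 lists were at adjusted p = 0.75 to 0.78, and none passed when adjusted over the list alone. Without the root 24 h pair, all of them but the glutathione S-transferase list lost the threshold. Heat shock then stood at 0.12, iron deficiency at 0.18, ribosomal proteins at -0.043, nitrate genes at -0.029 and histones at -0.020. In the 8 h pair that remains, glutathione S-transferase, heat shock and iron deficiency genes had opposite signs in the 2 fractions. The glutathione S-transferase medians there were -0.27 in total and 0.44 in polysomal RNA, with 26 of 38 genes of opposite sign. Its passing without the 24 h pair therefore does not show a response shared by both fractions. In shoots all 9 early stress factor genes were lower (median -0.35, adjusted p = 3.8e-08, adjusted p = 0.48 with an estimated correlation), and 7 of them passed when adjusted over the list alone. All 5 dawn clock genes were lower in shoots (median -0.53, adjusted p = 9.8e-07, adjusted p = 0.48 with an estimated correlation), 4 of them when adjusted over the list alone. All 8 dusk clock genes were higher there (median 0.19, adjusted p = 0.00042, adjusted p = 0.48 with an estimated correlation), 1 of them when adjusted over the list alone, but the list did not pass without the shoot 8 h pair (median 0.07, adjusted p = 0.12). Ribosomal protein (42 of 46, median -0.13, adjusted p = 1.0e-05), chaperone (10 of 10, median -0.13, adjusted p = 0.0023), flavonoid (12 of 12, median -0.12, adjusted p = 0.0039) and salicylate defence genes (11 of 15, median -0.14, adjusted p = 0.0085) were lower in shoots. All 4 sugar starvation genes were higher there (median 0.61, adjusted p = 0.00048). These 5 lists were at adjusted p = 0.48 to 0.73 with an estimated correlation, and 0, 1, 0, 0 and 2 genes passed when adjusted over the list alone. Of 24 photosynthesis genes 23 were lower (median -0.14, adjusted p = 0.0023, adjusted p = 0.83 with an estimated correlation, 0 when adjusted over the list alone). The median was -0.0084 after quantile normalization (adjusted p = 0.38) and 0.12 without the shoot 24 h pair (adjusted p = 0.012). Without that pair chaperone and flavonoid genes were at adjusted p = 0.36 and 0.29, and without the shoot 8 h pair salicylate genes at 0.45. The difference between roots and shoots, tested directly, also gave 0 of 21060 genes. An unadjusted p under 0.05 was found for 804, against 1053 expected with no change. All 46 cytosolic ribosomal protein genes were higher in roots relative to shoots (median 0.22, adjusted p = 1.2e-07, adjusted p = 0.53 with an estimated correlation; none when adjusted over the list alone), but not without the root 24 h pair (median 0.07, adjusted p = 0.18). Without the shoot 8 h pair only 1 shoot pair is left. The genes that then stood out in the difference did so mainly through 1 array, the polysomal control of shoots at 24 h.

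GSH did not change the polysomal to total ratio of any gene, relative to other genes, past the threshold. In limma 0 of 21060 genes passed, with 1353 at an unadjusted p under 0.05. Each array was scaled on its own, and the share of RNA in polysomes was not used. A change of polysome loading common to all genes is therefore removed before this test, which cannot decide on it. With camera, 11 of the 12 sulfur starvation markers had a higher ratio with GSH (median 0.28, adjusted p = 0.0052, adjusted p = 0.97 with an estimated correlation; none when adjusted over the list alone). All 10 iron deficiency genes had a higher ratio (median 0.32, adjusted p = 0.00094, adjusted p = 0.97 with an estimated correlation; none when adjusted over the list alone), and 38 of 46 ribosomal protein genes a lower one (median -0.16, adjusted p = 0.0021, adjusted p = 0.97 with an estimated correlation; none when adjusted over the list alone). The ratio was also higher for 30 of 38 glutathione S-transferase genes (median 0.17, adjusted p = 0.00094) and 14 of 21 sulfate genes (median 0.08, adjusted p = 0.020). Both were at adjusted p = 0.97 with an estimated correlation, and none of their genes passed when adjusted over the list alone. These directions follow the fraction labels and include the doubted total RNA pair of roots at 8 h. Without that pair none of the 5 lists passed. The glutathione S-transferase median was then 0.025, with 21 of 38 higher (adjusted p = 0.83), and the sulfate median 0.07 (adjusted p = 0.093). The sulfur starvation median was -0.031, with 5 of 12 higher (adjusted p = 0.83), the iron deficiency median 0.16 (adjusted p = 0.10) and the ribosomal protein median -0.14 (adjusted p = 0.090). Without the root 24 h pair the ribosomal protein median was -0.038 (adjusted p = 0.73). The sulfate list did not pass without the root 24 h or shoot 24 h pair either (adjusted p = 0.19 and 0.087). By pair, the sulfur starvation ratio had medians of 0.80 in roots at 8 h, -0.12 in roots at 24 h, -0.047 in shoots at 8 h and 0.04 in shoots at 24 h. The ribosomal protein ratio was -0.19 and -0.48 in roots but 0.08 in shoots at 8 h, where 36 of 46 were higher, and -0.035 in shoots at 24 h; the difference between organs was not tested.

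Roots and shoots of the same time and treatment, compared in total RNA, differed in most genes. All 17 root markers were higher in roots and all 24 photosynthesis genes lower, past the threshold (medians 7.01 and -6.35; camera adjusted p = 5.1e-06 and 1.9e-15, and adjusted p = 0.58 for both with an estimated correlation), and all 17 and 24 passed when adjusted over the list alone. All 5 dawn clock genes were lower in roots past the threshold (median -1.84, camera adjusted p = 0.021, adjusted p = 0.64 with an estimated correlation, 5 when adjusted over the list alone). Limma called 15014 of 21229 genes, 9276 higher in roots and 5738 lower; each pair lies on 1 slide, and 16744 and 14669 genes were called within the slides of 8 and 24 h. The root hair regulator gene RSL4 was at least 147.5-fold higher in roots, and AGP30 (AT2G33790), of root cell walls, was higher by 11.87 ± 0.50 (SE, adjusted p = 6.0e-06, 4 of 4 pairs), with 2 of its 4 shoot arrays well above background. AT1G52070, AT1G52050, BGLU35 and AT5G60530 were higher by 11.69, 10.33, 10.55 and 10.20, each well above background on 1 of 4 shoot arrays, and AT1G52060, AT2G39040, AT1G50060, AT5G14020 and AT1G19900 at least 506.5-fold, 451.6-fold, 396.2-fold, 237.7-fold and 416.8-fold. In shoots the myrosinase genes TGG1 and TGG2 were higher (-12.47 and -12.83 in roots minus shoots), as were GER3 (-12.55), FBA5 (-13.31) and AT1G23130 (-13.73); of the 4 root arrays, TGG2 and FBA5 were well above background on 2 and AT1G23130 on 1. AT1G33811, AT4G22513, CRR7, AT1G11850 and AT1G66100 were at least 1615.0-fold, 1704.4-fold, 1843.8-fold, 3647.9-fold and 5555.2-fold lower in roots. Sulfate transporter genes split by organ: SULTR1;1 was at least 62.3-fold higher and SULTR1;2 5.46 ± 0.32 higher in roots, and SULTR3;1 was -6.70 ± 0.17 (SE; adjusted p = 1.3e-06). Of 21 sulfate genes 8 were called higher and 6 lower, and 14 passed when adjusted over the list alone; of 13 glutathione metabolism genes 6 were higher and 3 lower, 9 when adjusted over the list alone. Chloroplast glutathione reductase (GR, AT3G54660) was -1.77 ± 0.11 and cytosolic GR1 1.32 ± 0.15.

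Between 8 and 24 h, total RNA changed widely, and dawn clock genes fell. The transfer in the morning ties time in the medium to time of day, so these cannot be told apart here. At 24 h it was morning again, so a fall of genes listed as peaking around dawn is not what their peak time would give. Dusk clock genes had median changes of 0.24 in total and 0.66 in polysomal RNA, but only 1 of the 8, PRR5, had the same direction in both. The cause of these changes was not tested. Limma called 8638 of 21229 genes, 3954 higher and 4684 lower at 24 h. LHY (AT1G01060) fell by 2.96 ± 0.22 (SE, adjusted p = 0.0054, lower in 4 of 4 pairs) and CCA1 fell by 2.49 ± 0.20 (adjusted p = 0.0059), both morning clock genes; in polysomal RNA LHY fell by 0.98 (adjusted p = 0.023) and CCA1 stood at -0.32 (adjusted p = 0.60). Of the 5 dawn clock genes 4 fell (median -1.62, camera adjusted p = 0.032, adjusted p = 0.88 with an estimated correlation, 4 when adjusted over the list alone). Of 9 heat shock genes 7 fell (median -1.06, adjusted p = 0.040, adjusted p = 0.88 with an estimated correlation and 0.063 after quantile normalization, 7 when adjusted over the list alone). Of the iron deficiency genes 7 of 10 fell (median -1.52, camera adjusted p = 0.016, adjusted p = 0.88 with an estimated correlation, 7 when adjusted over the list alone), among them OPT3 (-2.55, but -0.061 in polysomal RNA, adjusted p = 0.86). Of the flavonoid and anthocyanin genes 5 of 12 fell (median -1.02, adjusted p = 0.016, adjusted p = 0.88 with an estimated correlation, 5 when adjusted over the list alone), among them DFR (-2.45, and -3.51 in polysomal RNA, adjusted p = 0.013). All 14 aliphatic glucosinolate genes were lower and 8 fell (median -0.72, camera adjusted p = 0.0068, adjusted p = 0.88 with an estimated correlation, 9 when adjusted over the list alone). Of 24 photosynthesis genes 9 fell and 2 rose (median -0.40, adjusted p = 0.0497, adjusted p = 0.88 with an estimated correlation and 0.62 after quantile normalization, 11 when adjusted over the list alone). Without the root control pair the adjusted p was 0.075 for dawn clock, 0.10 for heat shock, 0.092 for flavonoid and 0.11 for photosynthesis genes; without the shoot control pair it was 0.11 for heat shock and without the root GSH pair 0.21 for photosynthesis genes. The list medians in polysomal RNA were -0.98 for dawn clock, -1.15 for heat shock, -0.71 for iron deficiency, -1.16 for flavonoid, -0.015 for aliphatic glucosinolate and 0.16 for photosynthesis genes. The jasmonate-induced genes JRG21 (AT3G55970) and NATA1 (AT2G39030) fell by 3.18 and 3.13 in total RNA, and by 2.26 and 2.31 in polysomal RNA (adjusted p = 0.012 and 0.011). AT2G38240 (-3.25), AT4G09450 (at least 2.69-fold), AT5MAT (-2.88), EXT13 (-2.84), LRX3 (-3.08), ESP4 (-3.01) and FAF4 (-3.45) also fell; AT5MAT and EXT13 were well above background on 2 of 4 arrays at 24 h. AT3G63052 (6.16), AT1G49700 (5.21), AT1G68945 (3.95), AT5G50335 (3.47), AT2G16586 (3.44) and AT4G33467 (3.42) rose, and AT5G16460, AT3G59070, AT5G44306 and TET13 rose at least 5.57-fold, 4.80-fold, 2.34-fold and 2.64-fold. AT5G50335 was well above background on 2 of 4 arrays at 8 h.

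Most of these time changes ran the other way in polysomal RNA. Of the 8638 called genes 1212 (14%) had the same direction there, and r across 21229 genes was -0.59; LRX3, for example, was 2.54 higher and AT3G63052 -6.45 at 24 h in polysomal RNA. Each slide holds 1 fraction at 1 time, so slide and time cannot be told apart. Without the root GSH, shoot control or shoot GSH pair, 4205, 2428 and 3837 genes were called.

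Between polysomal and total RNA, limma called 0 of 21060 genes, with 210 at an unadjusted p under 0.05, against 1053 expected with no change. Each slide holds 1 fraction at 1 time, so within a time fraction and slide cannot be told apart. The times opposed each other: 9037 genes were called at 8 h alone and 7361 at 24 h alone. Of 5874 called at both, 5872 had opposite directions. The 2 with the same direction, named after their values were seen, were UGT76E12 (0.85 and 0.85) and AT2G36325 (0.49 and 0.66). Cytosolic ribosomal protein genes had a median of 0.33 at 8 h and -0.26 at 24 h, photosynthesis genes -0.26 and 0.44, and root markers -0.19 and 0.59. With both times together, 23 of 25 histone genes were higher in polysomal RNA (median 0.16, camera adjusted p = 0.0018, adjusted p = 0.36 with an estimated correlation), and none passed when adjusted over the list alone. Their medians were 0.08 at 8 h and 0.14 at 24 h, and an exchange of fraction labels at either time would set these against each other. Without the shoot 8 h GSH pair the histone list did not pass (median 0.09, adjusted p = 0.077). Glutathione S-transferase genes (32 of 38 higher, median 0.16, adjusted p = 0.0017) and root markers (14 of 17 higher, median 0.17, adjusted p = 0.015) passed too. The glutathione S-transferase median was 0.37 at 8 h but -0.18 at 24 h, so both pooled values average opposite signs and follow the fraction labels. Both were at adjusted p = 0.93 with an estimated correlation, and none of their genes passed when adjusted over the list alone. The first did not pass without the root 8 h GSH, shoot 8 h control or shoot 8 h GSH pair (adjusted p = 0.26, 0.30 and 0.26). The second did not pass without the root 24 h GSH, shoot 24 h control or shoot 24 h GSH pair (adjusted p = 0.13, 0.51 and 0.45).

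**Figure D3:**
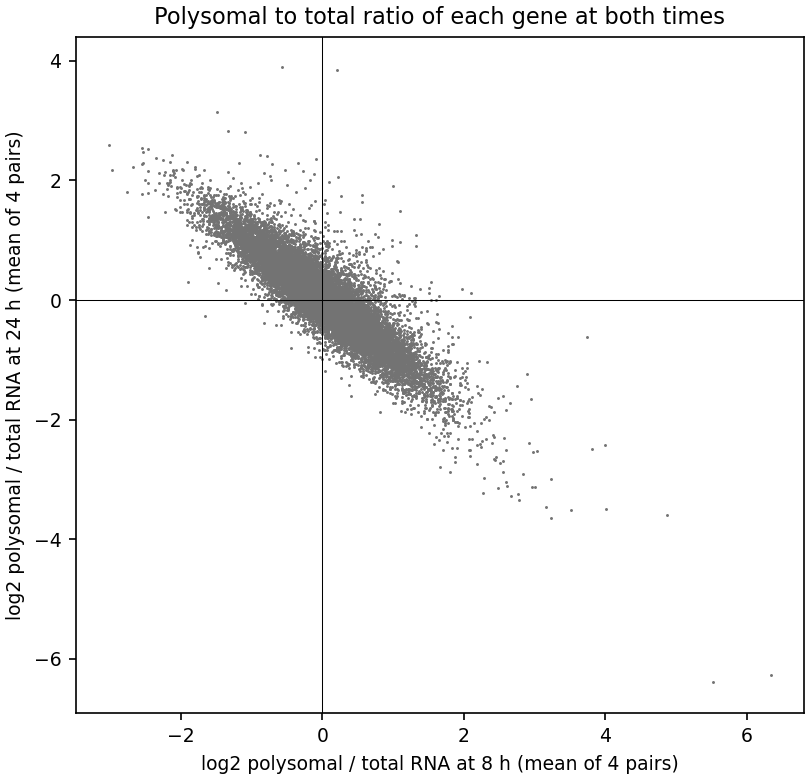
Log2 ratio of polysomal to total RNA of each gene at 8 h (x axis) and 24 h (y axis), each the mean of 4 pairs of arrays. The points fall along a descending line, with r = -0.89 across 21060 genes.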

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

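The tests on exchanged labels, on opposite responses, on the authors' lists, on non-coding RNA and on gene lists without a pair were chosen after the results were seen; those on other probes of a gene and on other splits of the arrays were not. The difference in the GSH response between roots and shoots, tested directly with camera, stood out for 10 gene lists, none with an estimated correlation (adjusted p of 0.53 to 0.57). Roots minus shoots was higher for heat shock (median 0.48), clock genes peaking around dawn (0.43), early stress transcription factors (0.28), cytosolic ribosomal proteins (0.22) and endoplasmic reticulum chaperones (0.21). It was lower for dark and sugar starvation (-0.66), clock genes peaking around dusk (-0.37), iron deficiency (-0.31), jasmonate (-0.26) and glutathione metabolism (-0.22). The root values include the doubted total RNA pair at 8 h. Only the dusk clock list passed without each pair in turn. Without the root 8 h pair, early stress factors and dawn clock genes were at adjusted p = 0.051 and sugar starvation at 0.31. Without the root 24 h pair, jasmonate and iron deficiency were at 0.83, glutathione metabolism at 0.36 and ribosomal proteins at 0.18. Without the shoot 8 h pair, iron deficiency was at 0.27, heat shock at 0.24, glutathione metabolism at 0.21 and jasmonate at 0.17. Without the shoot 24 h pair, chaperones and dawn clock genes were at 0.24, glutathione metabolism at 0.10 and sugar starvation at 0.083.

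The pair labelled total RNA of roots at 8 h moved against the other 3 root pairs. Of 34 genes at least 2-fold apart in one direction in those pairs, 0 had that direction in this pair, where their median was -1.75 against 1.59; this restates the pattern and decides nothing about its cause. The place of the arrays on the slide, which was turned round in this pair only, is argued against by 13 other probes of 12 such genes, which carried 80.8% of the change of the brightest probes in the other root pairs. Exchanged control and GSH labels and an opposite response of total RNA at 8 h both give a correlation below 0 between the fractions (-0.36 across genes). That correlation cannot tell them apart. The control array lay at position 3 and the GSH array at 4 in this pair, against 4 and 3 in the other root pairs. An exchange would give all root pairs the same order, but positions alone do not settle the labels, and both explanations stay open. The labels were kept. The authors' deposited table gives the same direction as the labels, but its folds follow the same labelled arrays (r = 0.9997 and 0.9996 with the unscaled ratio for higher and lower probes). Its direction therefore does not bear on an exchange.

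In the authors' deposited table, 2 polysomal lists of higher genes, roots at 8 h and shoots at 24 h, hold 3764 and 3491 entries against 10 lower entries each, and 5.53% of their probes stayed at least 2-fold higher once arrays were scaled to the 75th percentile. Folds taken with no scaling are argued against in shoots at 24 h, where the folds lay -0.469 from the unscaled ratio (0.22 for the 3 probes of the lower list), and stay open in roots at 8 h, where they lay at 0.0022 but the 4 probes of the lower list at 0.29. A single calibration factor, such as the share of RNA in polysomes named in the labels' protocols, could give the constant offsets of both lists in shoots at 8 h (-0.25) and in roots at 24 h (0.07), but is argued against as the whole account of the long lists, where the quartiles of the offset lay 0.0519 and 0.155 apart; such a factor with a further step stays open. Hybridisation or scanning is argued against by the spike-in transcripts, whose shifts were -0.31 and -0.0954 while the 75th percentile moved by 0.77 and 1.26. More messenger RNA per polysomal RNA as a response to GSH in every organ and time is argued against by shoots at 8 h, where the 75th percentile relative to the spike-ins moved by -0.58; such a change in those 2 conditions alone stays open.

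The change from 8 to 24 h in total RNA ran against that in polysomal RNA. Exchanged time labels of one fraction are argued against by the GSH changes, which correlated better with the same time in the other fraction in 3 of 4 pairs, the exception, roots at 8 h, being -0.29 on both sides. Probe-specific hybridisation between slides is argued against by 2858 other probes, which carried 95.4% of the difference. Against coding genes of like signal, 372 probes of non-coding RNA stood at a median of 0.72 (interquartile range 0.03 to 1.52) in polysomal against total RNA at 8 h and -0.88 (-1.76 to -0.23) at 24 h, but opposite signs follow from the reversal already seen over all genes (r = -0.89). An exchange of fraction labels at one time, a difference in RNA preparation between the slides and opposite time courses of the fractions therefore cannot be told apart here, and the last 2 were not tested.

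Exchanging the arrays of a pair gives 8 splits for the 4-pair comparisons, too few for a share under 0.05. GSH in total RNA, in polysomal RNA and on their ratio gave 0 genes in each of the 8 splits; with a real count of 0 every split gives as many, so these splits decide nothing. The real split gave 15014 genes for organ and 8638 for time, 1 of 8 splits each, and the highest of the others was 0. For polysomal against total RNA the real count was also 0, so that all 100 drawn splits gave at least as many and say nothing about chance. The highest, 13027, exchanged all pairs of 24 h, which points to a structure of the samples.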

How the results depend on the processing

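Normexp on median signals, polysomal arrays alone, total RNA arrays alone within an organ and time, either time alone, the fits within a slide and the list tests without each pair were chosen after seeing the data; total RNA arrays alone for GSH in roots and in shoots, which gave 0 genes, were not. The 6 GSH tests over several conditions, their difference between organs included, gave 0 genes with normexp, quantile normalization, all probes, other filters and limma's trend; leaving out a pair gave 0 to 10 in shoots, 0 to 3 for roots minus shoots and 0 elsewhere. Without the shoot 8 h pair, the lone shoot pair was assumed to vary like the root pairs. AT1G50040, AtS40-3, PHI-1, RBL7 and COR27 were then higher and CXXS2, AT1G33860, AT2G27270, AT5G23110 and RLP23 lower. AT3G04320, RLP23 and AT5G23110 differed between organs, but mainly through 1 array, the polysomal control of shoots at 24 h. They stood at 8.08, 8.11 and 9.28 on it and at most at 2.39, -5.47 and 1.06 on any other array. Leaving out a pair gave 13321 to 14448 genes for organ and 2428 to 8782 for time. Polysomal against total RNA went from 0 to 9037 at 8 h alone and 7361 at 24 h alone. With the slide as a random block it stayed at 0. That fit leaves out the pairs, so differences between organs enter its spread and its 0 is no check on the main fit. Of 55 list calls, 0 held with an estimated correlation, where the lowest adjusted p of 216 camera tests was 0.36. Root markers and photosynthesis genes between organs did not pass there either, so this setting decides nothing about a list. After quantile normalization 49 calls held, 6 were lost and 4 others were gained. Leaving out a pair kept 143 list results, lost 47 and reversed 10. The reversed medians ranged from -0.23 to 0.055 for jasmonate and -0.41 to 0.023 for iron deficiency in total RNA, -0.031 to 0.39 for sulfur starvation on the ratio, -0.40 to 0.0070 for jasmonate and -0.74 to 0.011 for iron deficiency in roots minus shoots, and -0.40 to 0.12 for photosynthesis in shoots. In roots they were -0.60 and 0.018 for jasmonate, -0.57 and 0.18 for iron deficiency, -0.043 and 0.23 for ribosomal proteins and -0.020 and 0.18 for histones. The reversals came without the root 24 h pair, except sulfur starvation (root 8 h) and photosynthesis (shoot 24 h). Each fit but that with the slide as a random block has pairs of conditions as its block, and no replicate numbers link the arrays.

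Counts of shared 2-fold genes moved with the settings; higher and lower fold minimums change them by construction, and the cause of the others was not tested. With a 1.5-fold minimum they were 102, 271, 136 and 463 for roots at 8 and 24 h and shoots at 8 and 24 h, and with a 3-fold minimum 3, 17, 4 and 12. Normexp gave 24 for roots at 24 h, 0 for shoots at 8 h and 38 for shoots at 24 h, and quantile normalization 9 for roots at 8 h. Requiring all 4 arrays well above background left 8 for roots and 10 for shoots at 8 h. Total RNA alone gave 258, 223, 144 and 188 and polysomal RNA alone 441, 170, 77 and 859.

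Under normexp PAP6 (-1.52), AT2G43440 (-1.54) and AT1G66860 (-0.85) reversed. They lie in roots at 8 h and shoots at 24 h. There the normexp median of all genes was -0.85 and -0.11 on the polysomal control array, against -1.24 and -1.40 on the polysomal GSH array. Whether that gave the reversals was not tested. In polysomal RNA 12 time changes had the other sign: AT1G49700 (-6.71), AT3G63052 (-6.45), AT5G44306 (-4.97), AT1G68945 (-3.56), AT3G59070 (-2.76), ESP4 (2.15) and LRX3 (2.54) passed the threshold there, and AT2G16586 (-2.99, adjusted p = 0.054 in limma), TET13 (-1.13, 0.18), AT5G50335 (-0.91, 0.26), AT5G16460 (-0.066, 0.93) and FAF4 (1.39, 0.11) did not. Of these, AT5G44306 and AT3G59070 were well above background on no polysomal array of 24 h and TET13 on 1 of 4, so their sizes are uncertain. Among named genes, 521 values under an alternative kept direction and threshold or spread, 60 moved and 12 lost the threshold. Signal over background limits the fold of dim genes, given as bounds.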

Other observations

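The genes shared by 3 of the 4 root pairs were listed, and those named here picked, after their values were seen. At least 1.5-fold in one direction in polysomal RNA at 8 h and in both fractions at 24 h were 104 root genes, of which 4 had that direction on the arrays labelled total RNA at 8 h. Those higher with GSH include UGT74E2 (1.69 in polysomal RNA at 8 h, 1.21 in total and 1.09 in polysomal RNA at 24 h), UGT87A2 (1.04, 0.61 and 0.60), GSTU25 (1.25, 1.63 and 1.25) and GSTU22 (1.26, 0.82 and 0.65). SAG13, a senescence-associated gene, was higher by 2.13, 2.78 and 1.01, CKX2, a cytokinin oxidase gene, by 3.48, 0.96 and 1.66, and the trypsin inhibitor gene TI1 by 1.43, 1.36 and 1.26. The sulfur genes LSU1 (1.44, 1.29 and 1.07) and SUFE2 (0.93, 0.62 and 0.59) were among them. Lower in all 3 were the glutamate receptor genes GLR2.3 (-1.31, -2.12 and -1.60) and GLR2.6 (-1.44, -1.88 and -1.50), FAMT (-0.94, -1.67 and -1.98) and the seed storage genes SESA3 (-0.83, -0.94 and -0.69) and SESA4 (-1.24, -0.89 and -0.82).

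Hypoxia genes in roots at 24 h had medians of 0.24 in total and 0.16 in polysomal RNA, at percentiles 98.76 and 100 of random lists. Cytosolic ribosomal protein genes had a median of 0.49 in total RNA there, 44 of 46 being higher, and 0.02 in polysomal RNA. In shoots at 8 h their medians were -0.19 and -0.08.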
